A study of Homo sapiens with 18 samples.

How the data were processed

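The series holds gene-level read counts from 18 RNA-seq libraries of H1975 and HCC827, 2 established human lung adenocarcinoma cell lines that carry activating EGFR mutations. The labels give each line 3 independent RNA samples, and each of the 6 RNA samples was sequenced on 3 platforms, which makes 6 groups of 3 libraries. Per the labels' protocols, Illumina libraries were made with a directional kit from 3.75 ng of mRNA with 11 PCR cycles and read as 75 nt pairs. Oxford Nanopore (ONT) cDNA libraries started from 1.5 ng of mRNA with 14 PCR cycles and ran on a PromethION. PacBio Iso-Seq libraries started from total RNA, were size-selected for molecules near 2 kb and amplified with 12 PCR cycles. Synthetic spike-in RNAs (sequins) had been added to the RNA. RNA input, library preparation and sequencer change together between platforms, so a platform difference belongs to the whole protocol.

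The deposited values are counts, whole numbers of reads or sequences per gene with no normalization, in 1 file per library. Per the submitters' processing notes, minimap2 2.17 and featureCounts were used with the GRCh38 build. Which tool served which platform, the version of featureCounts, its strand setting, its treatment of reads that match several places and the annotation release are not given in the sources used here. Per the file headers, the PacBio counts were taken from alignments of clustered sequences, so a PacBio count may stand for a cluster of reads. The header of PacBio HCC827 replicate 3 alone also names poly(A), and that of Illumina HCC827 replicate 3 alone names a repeat run. Because strand use is not stated, the counts of genes that overlap another gene on the opposite strand are uncertain, as are those of near-identical copies. Among the genes named below this holds for EGFR, MUC5B, CDK4, TSPAN31, LCP1, ELF3, LOX, COL1A1, SRFBP1, VIM, CDH1, TJP3, KRT18, FAP, SFTA2, NAPSA, NKX2-1, CDKN2A, SEC61G, UCHL1, ETV4, RSAD2, XAF1, FDFT1, CDKN1A, FAS, GAPDH, CORO1A, RPL10, RPL36A, RPS28, ATP5F1E, ATP5ME, RNU7-1, TUG1, MACF1, MDN1, NBEAL1, ANGPTL8, C14orf178, PRPH, TSIX, SH3GLB2, RAB11B-AS1, RETREG1-AS1, FARP1-AS1, PIGO-AS1, RFX5-AS1 and ARAP1-AS2. Overlap with another gene on the same strand leaves counts uncertain whatever the strand setting. Named genes with such overlap alone are C3, CEACAM5, CEACAM6, PSMB10, RPL28, RPL39, SNHG5, ARHGAP4, ZIM2-AS1, PTPRCAP, MIR711, MIR936, MIR6852 and MIR6716. Whether mitochondrial alignments were counted in the long-read files is not given in the sources used here.

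The Illumina files list 60738 features and the long-read files 58797, of which 76 are sequins and 45 are second copies of genes shared by the X and Y chromosomes, which were added to the X copy. Genes were matched by Ensembl identifier without its version: 58444 identifiers were shared, 41271 of them with the same version. Symbols, biotypes, GRCh38 coordinates and total exon length came from GENCODE release 44, which matched 60357 of 60617 Illumina genes and 58207 of 58676 long-read genes. Sequins stayed out of library sizes and gene tests. Every sequencing column belonged to a sample.

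Gene totals ranged from 81467393 to 116497461 counts in ONT libraries. Illumina totals lay between 33362018 and 40200473 counts except for HCC827 replicate 2, with 10020699. PacBio totals lay between 37795 and 54339 counts, and few PacBio genes had 10 or more counts per library. A gene with 0 counts was given a floor of 3 counts over its group of libraries, and its fold is then a lower bound. CPM values of genes are counts scaled to the effective library sizes of the fit they belong to, which cover its tested genes only, so the CPM of a gene differs between fits. For 1 to 3 counts the ratio of counts is given with an exact 95% Clopper-Pearson interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

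Tests used edgeR 4.0.16 in R 4.3.3 (trimmed mean of M values scaling, filterByExpr by group, robust quasi-likelihood fit, two-sided tests, Benjamini-Hochberg adjustment). A gene is called at an adjusted p below 0.05. The cell line difference, HCC827 over H1975, was fitted within each platform. Platform ratios were fitted on the 12 libraries of 2 platforms at a time with equal weight to each line, and the interaction term tested whether the cell line difference itself differed between platforms. The standard error of a log2 fold was taken from the fold and its quasi-likelihood F. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, adjusted over the lists of a use). A camera test compares a list with the other genes, whereas fry, an alternative, asks only whether the genes of a list move one way. Lists with fewer than 3 tested members were described without a test. Measures per library were compared by exact permutation tests, which treat libraries as independent although the platforms share RNA samples. Gene length slopes were tested by exact sign-flip tests over the 6 RNA samples. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

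The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names EGFR; the 6 highest and 6 lowest Illumina folds among protein-coding genes that were called in 1 direction on all 3 platforms with no overlap between the lines, a mean of 5 or more CPM (counts scaled to a common library total) and 10 or more counts in the lower line; up to 3 genes per line seen in all its 9 libraries and in none of the other line; and up to 4 called members of each list with the smallest adjusted p, with CDH1, VIM, NKX2-1 and CDKN2A as fixed members. For platform ratios it names the 5 highest and 5 lowest called genes at 50 CPM or more and up to 3 members of each list. For interactions it names the 5 highest and 5 lowest called genes at 10 CPM or more. After seeing the data, platform ratios of named genes with 1 to 3 counts in a line, or with 0 in only 1 line, were left out of the text, and fitted interactions of such genes are given without a standard error. XIST and Y-linked genes were skipped.

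The 27 lists for the cell line comparison cover the EGFR family and its ligands, MAPK output genes, epithelial junctions, mesenchymal genes, simple-epithelium keratins, basal or squamous, alveolar, airway secretory, ciliated, neuroendocrine and gastrointestinal lineage genes, class I antigen presentation, MHC class II, interferon-stimulated genes, NF-kB inflammatory genes, the cell cycle, p53 targets, NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein response, cancer-testis genes, neighbours of EGFR on chromosome 7, the CDKN2A region on chromosome 9, and hematopoietic, endothelial and fibroblast markers as other cell types. The 8 lists for the platform comparison cover replication-dependent histones, mitochondrial mRNAs, mitochondrial rRNAs, ribosomal proteins, nuclear genes of oxidative phosphorylation, small structured RNAs, long mRNAs and nuclear long non-coding RNAs. Symbols with no single match in GENCODE, 5 in all, were left out.

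Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, thinning every library to the smallest gene total of 37795 counts (37733 for measures per library), leaving out each RNA sample in turn, a replicate block, an estimated inter-gene correlation and fry. Chosen after seeing the data were the use of genes with the same identifier version only, leaving out mitochondrial genes, and summing PacBio libraries that differed by less than sampling noise. The pairing of libraries across platforms comes from the series design, in which the same RNA was sequenced on each platform. As a check, the deviations of the libraries of 1 RNA sample from their group means were correlated across genes between platforms: between ONT and Illumina r was 0.272, 0.0428 and 0.284 in H1975 and 0.591, 0.322 and 0.492 in HCC827. Between PacBio and Illumina r was 0.0451, 0.0628 and 0.0433 in H1975 and 0.363, 0.159 and 0.399 in HCC827. Between PacBio and ONT it was -0.0285, 0.0300 and 0.178, and 0.231, 0.146 and 0.263. An unmatched pair, ONT replicate 2 with Illumina replicate 3 of H1975, reached 0.0605. For H1975 with PacBio the check therefore decides little. Replicate numbers do not pair the cell lines, which were grown separately.

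The steps were tested on simulated counts drawn from the means and library sizes of the real data with 200 changed genes per comparison. Of the genes changed 2-fold, the fit recovered 78% in Illumina, 57% in ONT and 50% in PacBio for the cell line difference, and of those changed 4-fold 97%, 95% and 97%, among the genes that passed the filter. For platform ratios it recovered 76% and 94% (ONT over Illumina), 17% and 67% (PacBio over Illumina) and 13% and 55% (PacBio over ONT) of the 2-fold and 4-fold changes. Interactions of 4-fold were recovered in 80%, 14% and 14% of cases, in the same order. False calls made up at most 0.876% of the unchanged genes. Most simulated genes were unchanged, whereas in the real data 74.1% of tested genes were called between the lines in Illumina and 83.4% for ONT over Illumina. The simulated rates therefore do not cover errors of scaling that arise when many genes differ.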

Results

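Gene expression was measured as read counts per gene in H1975 and HCC827, human lung adenocarcinoma cell lines driven by mutant EGFR. Each line contributed 3 RNA samples. Each RNA sample was sequenced with Illumina short reads, Oxford Nanopore (ONT) cDNA long reads and PacBio Iso-Seq long reads, so that 18 libraries form 6 groups of 3. Gene totals were 81467393 to 116497461 counts per ONT library and 33362018 to 40200473 per Illumina library, with 10020699 in Illumina HCC827 replicate 2. PacBio libraries held 37795 to 54339 counts. In PacBio 996 ± 223 genes (mean ± SD, n = 6 libraries) reached 10 counts, against 23618 ± 2316 in Illumina and 26286 ± 1051 in ONT. Log2 folds are given with their standard errors from fits of 3 libraries per line, and adjusted p values of single genes are from edgeR.

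Within PacBio, H1975 replicates 2 and 3 differed by less than sampling noise (mean chi-square per gene 0.551 over genes with 20 or more counts), as did HCC827 replicates 1 and 2 (0.673), whereas the other pairs of a line ranged from 1.33 to 4.88. Across genes, the small differences within the HCC827 pair had r = 0.397 with those of the same RNA samples on Illumina and 0.148 on ONT, and those within the H1975 pair 0.0636 and 0.115. PacBio values below use all 6 libraries. Each close pair was counted as 1 sample only for genes between the lines and for measures per library. Of the named genes fitted that way between the lines, 18 kept their direction and side of the threshold and 5 lost the call. List tests, platform ratios, length slopes and interactions with PacBio were not repeated so, and their p values may be too small. PacBio HCC827 replicate 3 stood apart from replicates 1 and 2 of its line, with mean chi-squares of 4.41 and 4.88.

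The first comparison asks how the 2 cell lines differ. EGFR (ENSG00000146648; GRCh38 chromosome 7, 55019017 to 55211628), the receptor tyrosine kinase mutated in both lines, was higher in HCC827 on every platform. Illumina gave 381 ± 22.8 CPM in H1975 and 3296 ± 505 CPM in HCC827 (mean ± SD, n = 3 each), a log2 fold of 3.11 ± 0.13 (adjusted p = 6.36e-11). ONT gave 3.52 ± 0.23 (adjusted p = 4.66e-07), and PacBio 3.21 ± 0.37 (adjusted p = 0.00152) from 28 and 243 counts. MUC5B, a gel-forming airway mucin (chromosome 11, 1223066 to 1262172), was higher in HCC827 on all 3 platforms, with 9.53 ± 0.23 in Illumina, 7.75 ± 0.30 in ONT and at least 31.6-fold in PacBio, where H1975 had 0 counts.

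Other genes of HCC827 were CDK4, the cyclin D-dependent kinase (chromosome 12, 57747727 to 57756013; Illumina 4.51 ± 0.13, PacBio 2.78 ± 0.44), and the tetraspanin TSPAN31 (57738013 to 57750219; 4.41 ± 0.12 and 2.80 ± 0.44). Further genes were the actin-bundling protein LCP1 (chromosome 13, 46125920 to 46211871; 4.46 ± 0.11 and 2.98 ± 0.41) and ELF3, an epithelial transcription factor (chromosome 1, 202007945 to 202017183; 4.38 ± 0.15 and 2.29 ± 0.40). CDK4 and TSPAN31 overlap at their ends and had nearly equal long-read counts (18 and 18 in PacBio H1975, 111 and 113 in PacBio HCC827), so the separate values are uncertain. LANCL2, next to EGFR on chromosome 7 (55365337 to 55433737), was higher by 4.37 ± 0.11 in Illumina, and its 2 and 43 PacBio counts give a ratio of 23.5 (95% counting interval 6.12 to 200.2). The call of ELF3 in PacBio was lost without H1975 replicate 2 and when close PacBio pairs were summed (adjusted p = 0.0571).

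Genes of H1975 included the collagen crosslinking enzyme LOX (chromosome 5, 122063195 to 122078413; Illumina -6.79 ± 0.14, at least 14.4-fold lower in PacBio HCC827) and type I collagen COL1A1 (chromosome 17, 50184101 to 50201632; -4.55 ± 0.14, with 72 and 3 PacBio counts, a ratio of 22.0, interval 7.22 to 109.0). They also included the glycoprotein GPNMB (chromosome 7, 23235967 to 23275108; -3.28 ± 0.14) and SRFBP1 (chromosome 5, 121961975 to 122075570; -2.82 ± 0.11), which overlaps LOX and is uncertain for that reason. PacBio calls of GPNMB and SRFBP1 were lost without H1975 replicate 2, and those of LOX and SRFBP1 without H1975 replicate 3. Complement C3 (chromosome 19, 6677704 to 6730562) was lower in HCC827 by -4.81 ± 0.17 in Illumina, -1.26 ± 0.15 in ONT and -2.76 ± 0.33 in PacBio. The difference between the ONT and Illumina folds of C3 was itself called (3.70 ± 0.23, adjusted p = 1.39e-08). C3 overlaps another gene on the same strand, so its counts are uncertain. Leaving aside XIST, Y-linked genes and genes without a symbol, only 1 gene per line was seen in all its 9 libraries and none of the other. These were MIR711, inside COL7A1, in H1975 (at least 14.5-fold in Illumina) and FARP1-AS1 in HCC827 (at least 109-fold in Illumina). Each overlaps a host gene and is uncertain.

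**Figure D1:**
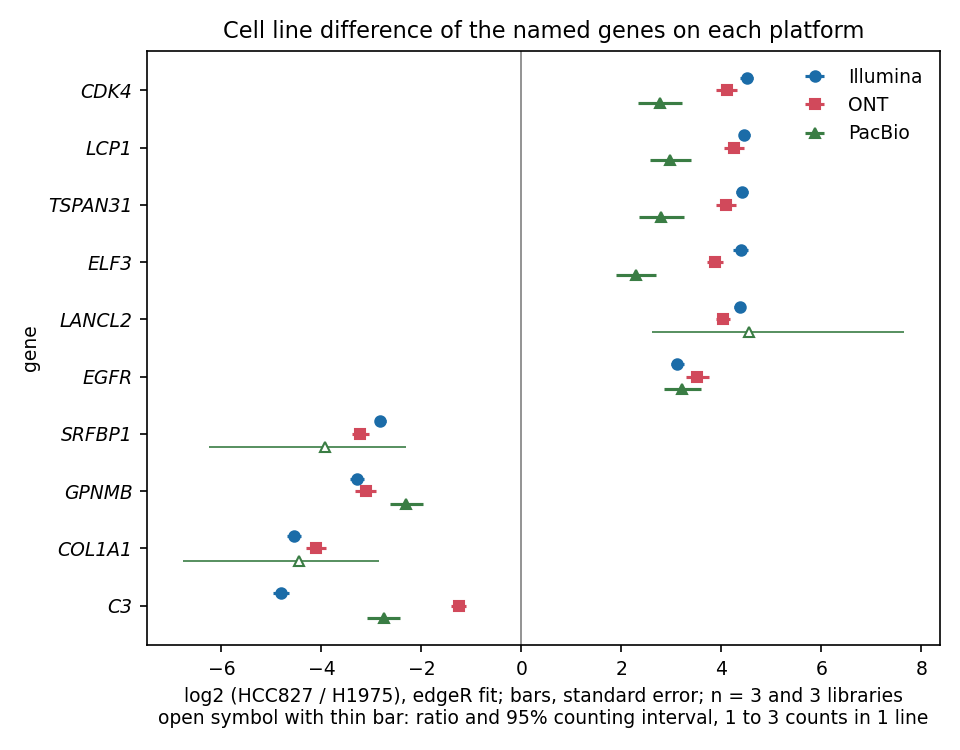
Log2 fold of HCC827 over H1975 (horizontal axis) for EGFR and the named genes with the most extreme Illumina folds that had counts in both lines on every platform (vertical axis), with circles for Illumina, squares for ONT and triangles for PacBio and bars of 1 standard error (n = 3 libraries per line). Open symbols mark genes with 1 to 3 counts in a line, drawn with a 95% counting interval; C3 shows the widest gap between Illumina (-4.81) and ONT (-1.26).

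Mesenchymal genes, which encode matrix and cytoskeletal proteins, were lower in HCC827. Of 25 tested in Illumina 23 were lower and 1 higher, with a median log2 fold of -2.71 (camera adjusted p = 3.05e-13; adjusted p = 0.386 with an estimated correlation). VIM, the intermediate filament of mesenchymal cells, fell by 4.33 ± 0.15, and the collagen COL5A1 by 7.97 ± 0.16. ONT placed 21 of 25 lower (adjusted p = 1.03e-15, and 0.0418 as an adjusted p with an estimated correlation). All 5 members tested in PacBio were lower, with a median of -4.31, or -3.85 with genes at 0 counts at their bound (camera adjusted p = 5.35e-08; adjusted p = 0.0547 with an estimated correlation). Fibroblast markers, listed as another cell type, had 4 of 8 lower and 1 higher (median -0.98, camera adjusted p = 0.156), among them SFRP4 (-6.00 ± 0.14) and FAP (-3.32 ± 0.35).

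Epithelial genes moved the other way. Of 28 junction genes in Illumina 23 were higher in HCC827 and 2 lower (median 1.25, camera adjusted p = 4.84e-07; adjusted p = 0.362 with an estimated correlation). The tight junction proteins CLDN3 (3.57 ± 0.14) and TJP3 (3.16 ± 0.16) led. CDH1, the E-cadherin of adherens junctions, had 0.71 ± 0.10 in Illumina and 0.76 ± 0.16 in ONT, and in PacBio 0.34 ± 0.29 did not pass the test (adjusted p = 0.447). After thinning to PacBio depth the Illumina fold of CDH1 turned to -0.18 and did not pass the test (adjusted p = 0.641). Genes tested in both fits moved by a median of -0.55 under that thinning, so the change was not particular to CDH1. The simple-epithelium keratins were higher in 6 of 6 (median 2.25, camera adjusted p = 0.000199; adjusted p = 0.408 with an estimated correlation), including KRT18 (2.58 ± 0.16), which overlaps KRT8, and KRT19 (2.32 ± 0.17). None of the 5 keratins tested in PacBio was called over all genes, against 4 adjusted over the list alone (edgeR; 326 of 901 genes had an unadjusted p below 0.05, and DESeq2 and limma-voom called 133 and 88 of all genes).

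Airway secretory genes had 11 of 14 higher and 0 lower in Illumina (median 4.79, camera adjusted p = 3.2e-07; adjusted p = 0.359 with an estimated correlation). The surface glycoproteins CEACAM6 (7.25 ± 0.20) and CEACAM5 (10.41 ± 0.30) and the iron-siderophore carrier LCN2 (9.04 ± 0.27) were among them. Alveolar lineage genes had 10 of 16 higher and 4 lower (median 1.52, camera adjusted p = 0.0176; adjusted p = 0.408 with an estimated correlation). SFTA2, a surfactant-associated protein, reached 10.97 ± 0.26, the protease NAPSA 6.48 ± 0.18, and NKX2-1, the transcription factor of lung epithelium, 1.83 ± 0.10, while LAMP3, of alveolar lamellar bodies, was lower (-2.06 ± 0.11). Gastrointestinal lineage genes were higher in 5 of 6 (median 3.11, camera adjusted p = 0.000114; adjusted p = 0.386 with an estimated correlation), among them the transcription factor HNF4G (3.35 ± 0.13). Basal or squamous genes had 6 of 12 higher and 5 lower (median 0.39, mean -0.10, camera adjusted p = 0.858), with SOX2 higher (2.65 ± 0.10) and TP63 lower (-2.54 ± 0.11). Ciliated cell genes had 4 of 11 higher and 4 lower (median -0.01, camera adjusted p = 0.886), and neuroendocrine genes 1 of 6 higher and 4 lower (median -1.42, camera adjusted p = 0.156), including UCHL1 (-2.73 ± 0.35).

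The neighbours of EGFR on chromosome 7 were higher in 11 of 11 (median 1.98, camera adjusted p = 3.57e-08; adjusted p = 0.0905 with an estimated correlation). Among them were SEC61G, a subunit of the protein translocation channel (3.71 ± 0.11), and VOPP1 (3.28 ± 0.12). ONT gave 10 of 12 higher and 0 lower (camera adjusted p = 1.85e-09, and 0.0418 as an adjusted p with an estimated correlation), and PacBio 5 of 5 (6.24e-05; adjusted p = 0.361 with an estimated correlation). In the CDKN2A region of chromosome 9, 4 of 8 genes were higher and 2 lower (median 0.39, camera adjusted p = 0.166), with the cell cycle inhibitor CDKN2A at 3.29 ± 0.11. Members of the EGFR family and their ligands split, with 6 of 12 higher and 4 lower (median 0.61, mean -0.02, camera adjusted p = 0.512). The ligands TGFA (-1.99 ± 0.12) and HBEGF (-2.13 ± 0.18) were lower and EREG (1.30 ± 0.12) was higher in HCC827. MAPK output genes had 11 of 18 higher and 5 lower (median 0.48, camera adjusted p = 0.105), with the feedback inhibitor SPRY1 (1.98 ± 0.12) and the transcription factor ETV4 (2.11 ± 0.14).

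Interferon-stimulated genes were lower in 27 of 42 and higher in 10 (median -0.56, camera adjusted p = 0.0122; adjusted p = 0.836 with an estimated correlation). Lower members included the antiviral RSAD2 (-3.61 ± 0.18) and IFIT5 (-1.87 ± 0.10) and the apoptosis factor XAF1 (-2.18 ± 0.12). Cholesterol synthesis genes were higher in 17 of 25 and lower in 4 (median 0.83, camera adjusted p = 0.00289; adjusted p = 0.408 with an estimated correlation). Higher members included the enzymes MVD (2.27 ± 0.13), FDFT1 (2.13 ± 0.13) and DHCR7 (2.00 ± 0.11). Class I antigen presentation genes had 9 of 19 higher and 7 lower (median 0.16, camera adjusted p = 0.771), from the peptidase ERAP2 (-4.53 ± 0.14) to the proteasome subunit PSMB10 (2.42 ± 0.12). MHC class II genes had 4 of 10 higher and 5 lower (median -0.51, camera adjusted p = 0.376), with the invariant chain CD74 at -3.10 ± 0.12. NF-kB inflammatory genes had 15 of 26 higher and 8 lower (median 0.59, camera adjusted p = 0.239), among them the chemokine CXCL5 (3.78 ± 0.15). Cell cycle genes had 21 of 34 higher and 9 lower (median 0.49, camera adjusted p = 0.105), with the anaphase activator CDC20 (2.96 ± 0.16) and the methylation factor UHRF1 (-1.96 ± 0.11).

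Stress and metabolic lists split between the lines. Of p53 targets 8 of 27 were higher and 11 lower (median -0.01, camera adjusted p = 0.721), with the cell cycle inhibitor CDKN1A at -2.11 ± 0.13 and the death receptor FAS at -1.87 ± 0.13. NRF2 targets had 11 of 26 higher and 9 lower (median -0.03, mean 0.07, camera adjusted p = 0.771), from the transporter ABCC2 (5.28 ± 0.12) to the heme-degrading enzyme HMOX1 (-3.06 ± 0.12). Hypoxia and glycolysis genes had 9 of 28 higher and 12 lower (median -0.18, camera adjusted p = 0.304), with the carbonic anhydrase CA12 (-6.01 ± 0.17), the glucose transporter SLC2A3 (-4.13 ± 0.12) and the glycolytic enzyme GAPDH (2.39 ± 0.16). Unfolded protein response genes had 7 of 21 higher and 8 lower (median 0.11, camera adjusted p = 0.858), and cancer-testis genes 2 of 6 higher and 4 lower (median -1.39, camera adjusted p = 0.218). CT45A1 of the latter had 6059 Illumina counts in H1975 and 0 in HCC827 (at least 1179-fold lower), and like XAGE1B (-1.36 ± 0.10) it has near-identical copies and is uncertain. Hematopoietic markers had 5 of 10 higher and 4 lower (median 0.33, mean -0.10, camera adjusted p = 0.743), with the actin regulator CORO1A at 2.96 ± 0.18 and the endotoxin receptor CD14 at -2.80 ± 0.18. Endothelial markers had 2 of 7 higher and 4 lower (median -1.14, camera adjusted p = 0.681), with the receptor KDR at -2.23 ± 0.25.

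Across all genes, Illumina tested 25711 and called 19061 (9293 higher and 9768 lower in HCC827). ONT tested 27366 and called 17163 (8503 and 8660), and PacBio tested 901 and called 206 (103 and 103). Of the 27 lists camera called 9 in Illumina and 9 in ONT, and 2 of 11 in PacBio. With an estimated correlation 0, 3 and 0 were called, the 3 of ONT being the mesenchymal, airway secretory and EGFR neighbour lists. With fry, which asks another question, 23, 19 and 6 were called. In ONT the ciliated, class I antigen presentation, p53, cancer-testis and hematopoietic lists had a median that differed in sign from their mean or test. Adjusted over the list alone, the number of called Illumina members was the same except for junction genes (26), airway secretory genes (12) and cell cycle genes (31). The PacBio count moved with single libraries: 24 without H1975 replicate 2, 33 without H1975 replicate 3, 79 and 75 without HCC827 replicates 1 and 2, and 336 without HCC827 replicate 3. With each close PacBio pair counted as 1 sample, 63 genes were called, 18 of them also among the 206.

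The platforms were then compared for the cell line folds of the same genes, including those of EGFR and C3 above. Over 23433 genes tested in both, ONT and Illumina folds had r = 0.902 (Spearman rho = 0.880) and the same sign in 85.9%. Of 13255 genes called on both, 6456 were higher on both, 6533 lower on both and 266 opposite; independent lists would share 2697 and 2908. PacBio and Illumina folds had r = 0.905 (rho = 0.871) over 897 genes, and of 203 called on both 101 were higher, 100 lower and 2 opposite, against 50.3 and 31.2 for independent lists. PacBio and ONT folds had r = 0.869 (rho = 0.813) over 901 genes, with 98 higher, 84 lower and 2 opposite of 184, against 42.4 and 26.2. These correlations run across genes, which are not independent replicates, and platforms share RNA samples, so part of the excess may come from deviations of those samples. Called on all 3 platforms were 183 genes, 180 of them in 1 direction. The difference between the folds of 2 platforms was itself called for 2105 of 29395 genes between ONT and Illumina, and for 1150, 1105 and 1101 without H1975 replicate 1, 2 and 3. Between PacBio and Illumina it was called for 4 of 19189 (32 with a block for RNA sample, 223 with DESeq2, 3890 with limma-voom). Between PacBio and ONT it was called for 5 of 24440 (99 with the block, 226 with DESeq2, 5721 with limma-voom).

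The second comparison asks what changes when the same RNA is sequenced by ONT in place of Illumina. Ribosomal protein genes were higher in ONT in 79 of 79, with a median log2 ratio of 3.74 (camera adjusted p = 2.1e-53; adjusted p = 0.0492 with an estimated correlation). RPL39 stood at 3029.5 ± 1355 CPM in ONT and 37.3 ± 20.7 CPM in Illumina (mean ± SD, n = 6), a ratio of 6.42 ± 0.09 (adjusted p = 7.2e-21), and RPL36A at 7.45 ± 0.10. Nuclear genes of oxidative phosphorylation were higher in 49 of 49 (median 3.45, camera adjusted p = 7.21e-32; adjusted p = 0.052 with an estimated correlation), with the ATP synthase subunits ATP5F1E (4.78 ± 0.09) and ATP5ME (4.55 ± 0.09). All 13 mitochondrial mRNAs and both mitochondrial rRNAs were listed at 0 counts in every ONT library, while MT-CO1, a cytochrome c oxidase subunit, had 6150.3 ± 1269.9 CPM in Illumina. Over all 37 mitochondrial genes the same RNA samples gave 15644059 counts in Illumina and 0 in ONT. These values argue against reading the ONT zeros as a lack of expression. Whether mitochondrial alignments were counted in the long-read files is not given in the sources used here, and no fold is given.

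Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were higher in ONT in 33 of 40 (median 2.19, camera adjusted p = 0.000173; adjusted p = 0.254 with an estimated correlation), with H4C12 at 5.14 ± 0.12 and H4C9 at 3.56 ± 0.11. Long mRNAs were lower in 47 of 50 and higher in 3 (median -2.58, camera adjusted p = 7.93e-12; adjusted p = 0.22 with an estimated correlation). HERC2, NBEAL1 and MDN1 were higher (5.07 ± 0.09, 4.30 ± 0.10 and 3.13 ± 0.10), and NBEAL1 overlaps the ribosomal protein pseudogene RPL12P16. Small structured RNAs had 10 of 18 higher and 2 lower (median 1.18, camera adjusted p = 0.538), with RNU7-1 of the histone processing complex at 3.95 ± 0.16. As a share of all counts the list was lower in ONT, 0.00293% ± 0.000901 against 0.0116% ± 0.00479 in Illumina (mean ± SD, n = 6; exact permutation p = 0.00216, adjusted p = 0.00292), so its direction is not settled. Nuclear long non-coding RNAs had 6 of 14 higher and 6 lower (median 0.28, camera adjusted p = 0.651), from SNHG5 (3.66 ± 0.09) to TUG1 (-3.05 ± 0.09). Among the highest ratios were those of the pseudogenes RPS29P3 (13.24 ± 0.16) and RPS27P17 (12.79 ± 0.17), near-identical copies of expressed genes whose counts are uncertain, as are those of RPS29P8, with 2 Illumina counts. In all, 24501 of 29395 genes were called, 12995 higher and 11506 lower in ONT, and 18242 by 2-fold or more, with a median of 0.12. Without HCC827 replicate 2 the balance turned, with 12488 higher, 12560 lower and a median of -0.03, and RLE scaling gave a median of 0.06. Among genes with the same identifier version in both annotations, a restriction chosen after seeing the data, 13203 of 16043 were called.

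The third comparison sets PacBio against Illumina. Ribosomal protein genes, higher in ONT, were lower in PacBio in 79 of 79 (median -4.74, or -4.50 with genes at 0 counts at their bound; camera adjusted p = 3.88e-54; adjusted p = 0.0228 with an estimated correlation), with RPL28 at -4.24 ± 0.18 and RPS4X at -5.18 ± 0.23. Oxidative phosphorylation genes were lower in 46 of 49, and in 48 adjusted over the list alone (median -7.63, or -4.04 with zeros at the bound; camera adjusted p = 2.51e-13; adjusted p = 0.128 with an estimated correlation). Mitochondrial mRNAs and rRNAs were again listed at 0, with the same limit. Long mRNAs were lower in 46 of 50, and in 47 adjusted over the list alone (median -3.23, or -3.04 with zeros at the bound; camera adjusted p = 7.26e-18; adjusted p = 0.0845 with an estimated correlation), with the cytoskeletal linker MACF1 at -3.76 ± 0.28. As a share of all counts the list was not lower in PacBio, with 1.62% ± 0.756 against 1.42% ± 0.318 in Illumina (mean ± SD, n = 6; exact permutation p = 0.578, adjusted p = 0.637), or 1.43% ± 0.825 with close pairs counted as 1 sample (n = 4, exact permutation p = 1).

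Nuclear long non-coding RNAs were lower in PacBio in 12 of 13 (median -7.41, or -3.94 with zeros at the bound; camera adjusted p = 3.67e-06; adjusted p = 0.0891 with an estimated correlation). Histones had 8 of 22 lower, or 7 adjusted over the list alone, and 0 higher; their median of -7.81 becomes -1.60 with zeros at the bound, and camera placed them above the other genes (adjusted p = 0.871) whereas fry gave a lower direction (adjusted p = 0.0269). The 3 small structured RNAs tested all had 0 PacBio counts, with a median of -12.49 that becomes -3.06 at the bound (camera adjusted p = 0.221). PTPRCAP, a phosphatase-associated protein gene inside the reach of CORO1B, was higher in PacBio by 6.64 ± 0.36 (48 PacBio and 162 Illumina counts), as were PIGO-AS1 (8.17 ± 0.71), RFX5-AS1 (6.87 ± 0.62), MIR936 (6.53 ± 0.46) and C14orf178 (6.29 ± 0.55); each overlaps a longer gene and is uncertain. In all, 9463 of 19189 genes were called, 1726 higher and 7737 lower, and 8377 by 2-fold or more. The share of higher calls was 18.2%, against 31.6% with DESeq2 and 45.8% with limma-voom. Because 5010 genes had 0 PacBio counts, the median over all genes was -1.73 as fitted and -0.62 with zeros at the bound. With genes of the same identifier version only, chosen after seeing the data, 5041 were called.

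The fourth comparison sets PacBio against ONT. Ribosomal protein genes were lower in PacBio in 79 of 79 (median -8.52, or -8.48 with zeros at the bound; camera adjusted p = 1.16e-68; adjusted p = 0.0579 with an estimated correlation), with RPL10 at 35.3 ± 4.44 CPM in PacBio and 9165 ± 3754 CPM in ONT (mean ± SD, n = 6), a ratio of -7.92 ± 0.17. Oxidative phosphorylation genes were lower in 49 of 49 (median -10.62, or -7.39 with zeros at the bound; camera adjusted p = 4.61e-38; adjusted p = 0.0579 with an estimated correlation). Histones were lower in 23 of 35 (median -9.36, or -2.01 with zeros at the bound; camera adjusted p = 0.0418; adjusted p = 0.553 with an estimated correlation and 0.0546 with RLE scaling). H4C9 was at least 27.3-fold and H1-2 at least 14.3-fold lower. Nuclear long non-coding RNAs were lower in 10 of 13 (median -6.26, or -5.28 with zeros at the bound; camera adjusted p = 0.000135; adjusted p = 0.0741 with an estimated correlation), SNHG5 by at least 167-fold.

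Long mRNAs showed 7 of 50 higher and 16 lower in PacBio than in ONT (median -1.10, or -0.90 with zeros at the bound), and camera placed the list above the other genes (adjusted p = 0.559). As a share of all counts the list was higher in PacBio, 1.62% ± 0.756 against 0.427% ± 0.0528 in ONT (mean ± SD, n = 6; exact permutation p = 0.0130, adjusted p = 0.0167; p = 0.0571 with close pairs counted as 1 sample), so its direction is not settled. Small structured RNAs had 3 of 15 lower and 0 higher, with a median of -8.32 that becomes 0 with zeros at the bound, and camera again gave the opposite sign (adjusted p = 0.925). Mitochondrial genes were listed at 0 on both platforms. The lowest ratios, all with 0 PacBio counts, were those of DGKI (15751 ± 4231 CPM in ONT), RPS28 (7334 ± 2289.6 CPM) and the pseudogenes RPL41P5, RPL41P1 and RPS28P4. The counts of these pseudogenes are uncertain, as is that of RPS28, which overlaps other genes. DGKI overlaps no exon of another gene, but whether the ONT reads counted for DGKI come from that gene was not tested. The highest were MIR6852 (8.57 ± 0.42), ANGPTL8 (7.47 ± 0.57), MIR936 (7.22 ± 0.55), ARAP1-AS2 (6.81 ± 0.34) and MIR6716 (6.58 ± 0.46), each within or across a longer gene and uncertain. In all, 11436 of 24440 genes were called, 3339 higher and 8097 lower, and 10736 by 2-fold or more. The higher share was 29.2%, against 61.9% of 20139 calls with limma-voom. With 9908 genes at 0 PacBio counts, the median over all genes was -4.44 as fitted and -0.04 with zeros at the bound.

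Gene classes took different shares of the counts on each platform. Pseudogenes took 26.8% ± 2.11 of ONT counts, 6.39% ± 0.920 of Illumina counts and 1.01% ± 0.0879 of PacBio counts (mean ± SD, n = 6). Ribosomal protein genes took 11.6% ± 1.62, 2.76% ± 0.814 and 0.417% ± 0.286. The 37 mitochondrial genes took 8.36% ± 1.22 in Illumina and 0 counts in the long-read files. Protein-coding genes took 60.3% in ONT, 76.04% in Illumina and 82.2% in PacBio. Each pair of platforms was fully separated for the pseudogene, ribosomal protein and protein-coding shares (exact permutation test, two-sided, p = 0.00216, adjusted p = 0.00292, the smallest the 6 against 6 design allows). These shares are of all gene counts, which in Illumina include the mitochondrial genes. The mean protein-coding shares of PacBio and Illumina differed by 6.14 percentage points. That is less than the mitochondrial share of any Illumina library (7.20% to 9.85%). Shares without mitochondrial counts were not tested, so whether PacBio and Illumina differ in protein-coding share without them is open. With close PacBio pairs counted as 1 sample, pseudogenes took 0.992% ± 0.0873 and ribosomal protein genes 0.465% ± 0.351 (n = 4, exact permutation p = 0.00952 against either platform, the smallest possible).

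**Figure D2:**
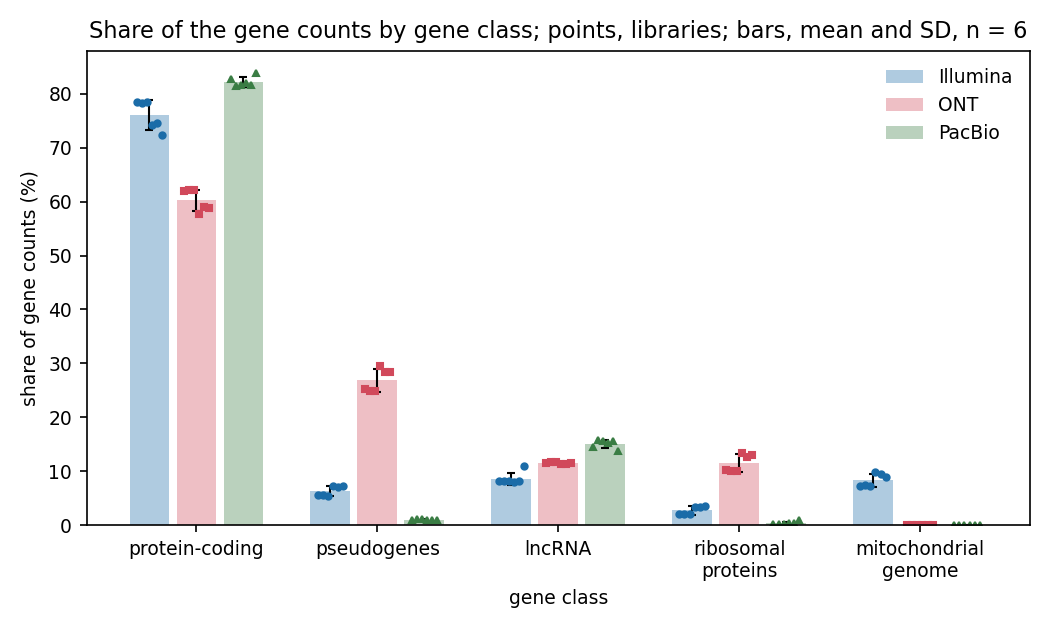
Share of gene counts (vertical axis, %) by gene class (horizontal axis) for Illumina, ONT and PacBio; points are the 6 libraries of a platform, bars their mean and black lines the SD. Pseudogenes reach 26.8% in ONT against 6.39% in Illumina and 1.01% in PacBio, and mitochondrial genes appear in Illumina only (8.36%), being listed at 0 on the other platforms.

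Genes with short exon unions took more of the ONT counts. Protein-coding genes of 1000 to 2000 nt took 12.7% ± 0.236 of protein-coding counts in ONT, 5.17% ± 0.713 in Illumina and 3.30% ± 0.758 in PacBio (mean ± SD, n = 6). Genes of 5000 to 10000 nt took 28.3% ± 0.401, 38.7% ± 1.27 and 43.0% ± 1.58. Per RNA sample, the log2 ratio of ONT to Illumina fell with log2 exon length, with a slope of -0.571 ± 0.0107 (mean ± SD, n = 6 RNA samples, below 0 in all 6; exact sign-flip p = 0.0313, the smallest possible). For PacBio over Illumina the slope was -0.258 ± 0.0872 (exact sign-flip p = 0.0313), but -0.0560 ± 0.0927 among genes with a mean of 50 or more counts (exact sign-flip p = 0.219). For PacBio over ONT it was 0.0738 ± 0.0355 (exact sign-flip p = 0.0313), and 0.368 ± 0.0428 among genes with a mean of 50 or more counts. Genes entered at a mean of 10 or more counts over both libraries, with 0.5 counts added to each. For PacBio over ONT 21901 to 24448 genes entered, although only 8980 to 11331 genes per library had any PacBio count. The slopes with PacBio therefore rest in large part on genes with 0 PacBio counts and depend on the level of the other platform.

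**Figure D3:**
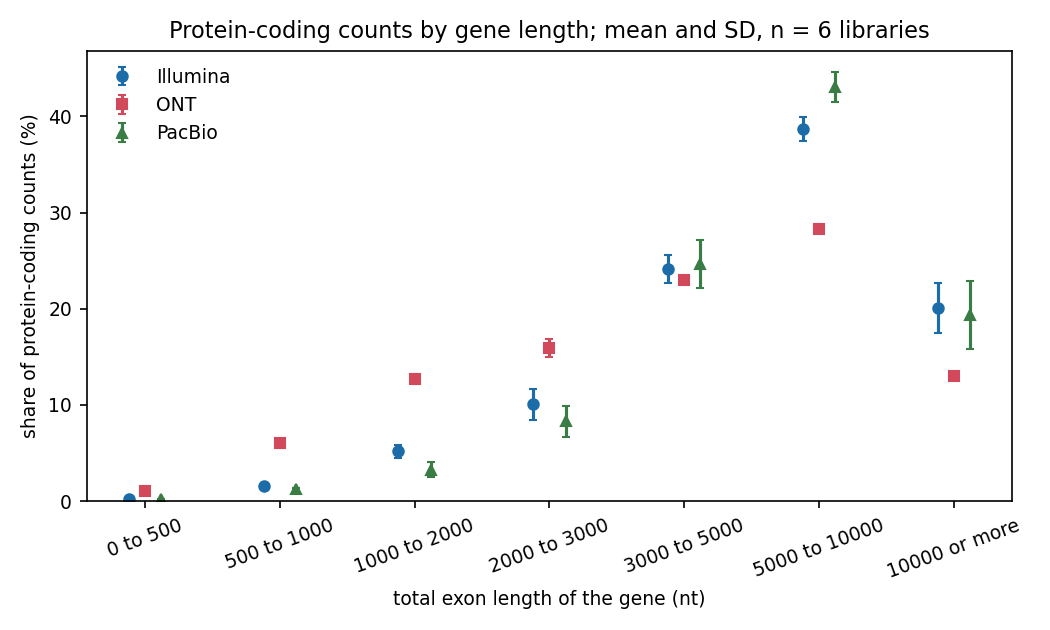
Share of protein-coding counts (vertical axis, %) by total exon length of the gene in nt (horizontal axis), as mean and SD over the 6 libraries of each platform. ONT lies above both other platforms below 3000 nt (12.7% against 5.17% and 3.30% at 1000 to 2000 nt) and below them from 5000 nt (28.3% against 38.7% and 43.0% at 5000 to 10000 nt).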

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

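The drawn splits and the differences between folds were planned tests; the restriction to the same identifier version and the 32 splits that part all RNA samples were tests chosen only after the result was seen. The cell line difference of 2105 genes differed between ONT and Illumina, tested as an interaction in edgeR on 12 libraries, with 1150, 1105 and 1101 without H1975 replicate 1, 2 and 3. Between PacBio and Illumina 4 genes were called (223 with DESeq2, 3890 with limma-voom) and between PacBio and ONT 5 (226 and 5721), so these counts do not rank the platform pairs. Differences below are log2 folds on the first platform minus those on the second.

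Between ONT and Illumina, positive differences were those of the glutamate receptor GRIK2 (5.74 ± 0.58), the axon guidance receptor ROBO1 (4.48 ± 0.44), the pseudogene RPLP0P2 (4.03 ± 0.31) and the copine CPNE4 (3.99 ± 0.20). GRIK2 varied widely within ONT HCC827, at 21.1 ± 14.7 CPM (mean ± SD, n = 3), so the size of its difference is uncertain. CPNE4 stood at 4.78 and 30.1 CPM in ONT H1975 and HCC827 and at 5.22 and 2.05 CPM in Illumina. In the other direction were the intermediate filament PRPH (-4.45 ± 0.62) and the pseudogene PRODHLP (-4.55 ± 0.36). The fitted differences of the metallothionein pseudogene MT1L (8.07, with 0 Illumina counts in HCC827), the antisense RNA TSIX (-4.14, with 3 Illumina counts in H1975), RETREG1-AS1 (-6.51, with 0 ONT counts in HCC827) and ZIM2-AS1 (-8.08, with 1 ONT count in HCC827) depend on the prior count of the fit, so their size and rank are open. Pseudogenes and antisense RNAs among these share sequence or position with other genes and are uncertain. The call of TSIX was lost with limma-voom and without replicate 1 or replicate 3 of either line.

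Between PacBio and Illumina, the antisense RNA RAB11B-AS1 differed by 3.06 ± 0.45, SH3GLB2 by -1.92 ± 0.36, the GTPase activator ARHGAP4 by -3.01 ± 0.56 and the cystathionine synthase CBS by a fitted -4.57, with 2 PacBio counts of CBS in HCC827. CBS stood at 80.1 and 9.67 CPM in PacBio H1975 and HCC827 and at 49.1 and 151 CPM in Illumina. Between PacBio and ONT, ARHGAP4 differed by -3.26 ± 0.47 and CBS by a fitted -4.31. Between PacBio and Illumina, RAB11B-AS1 was lost without HCC827 replicate 3 (adjusted p = 0.0617), SH3GLB2 and ARHGAP4 with RLE scaling (0.127 and 0.0885), without a filter (0.200 and 0.145), with the same identifier version (0.247 and 0.125) and whenever 1 RNA sample was left out, as was CBS. Between PacBio and ONT, CBS was lost whenever 1 RNA sample was left out (adjusted p 0.0561 to 0.125), and ARHGAP4 in each such fit (0.0561 to 0.0997) except that without HCC827 replicate 2.

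Splits that mix the platform labels within each line were drawn 100 times, the real one included. For ONT over Illumina 1 gave as many genes as the real 24501 (highest other 16659), for PacBio over Illumina 1 as many as 9463 (highest other 319) and for PacBio over ONT 1 as many as 11436 (highest other 3729). In each of these 3 comparisons the real platforms alone make up the share of 0.01. The other draws put the platform ratio into the spread, which lowers their counts, so they do not exclude chance. For the ONT and Illumina interaction 3 gave as many as the real 2105 (highest other 16659), and for the interactions with PacBio 14 reached 4 (highest other 319) and 45 reached 5 (highest other 3729). Splits with the highest counts kept the true platforms as groups in 1 line only, so their interaction carries the platform effect, a structure of the samples. Most draws leave both libraries of some RNA samples on 1 side, whereas 32 splits, the real one included, part all 6 RNA samples. Of these 1 gave as many as the real platform count in each comparison (highest other 16659 for ONT over Illumina, 547 for PacBio over Illumina and 3729 for PacBio over ONT). With the pairing kept, the real split alone makes up the share of 0.03125, which has the same limit and does not exclude chance. For the interactions these 32 decide nothing, since the split that swaps the platforms in 1 line turns the platform ratio into the interaction (24501, 9463 and 11436 genes), which keeps the share above 0.05. The draws also mix the platform ratio into the interaction or into the spread, so chance is left open for all 3 interactions. For the cell line difference the 10 splits are too few for a share below 0.05; the real counts were 19061, 17163 and 206, and the highest other was 0 on each platform.

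Sequins, the synthetic spike-in RNAs kept out of the gene tests, took 2.20% ± 0.886 of counts in Illumina, 0.841% ± 0.313 in ONT and 0.0686% ± 0.0307 in PacBio (mean ± SD, n = 6), where 18 to 52 counts fell on them. Over 61 sequins with 10 or more counts, the folds between the lines had r = 0.944 between ONT and Illumina, with a slope of 0.971 and the same sign in 53.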

How the results depend on the processing

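The restriction to genes of the same identifier version and the summing of close PacBio pairs were tests chosen after seeing the data. Of the alternatives for named genes between the lines, 2902 kept direction and side of the threshold, 29 lost the call, 2 gained it and 1 changed sign: CDH1 in thinned Illumina, at -0.18 (adjusted p = 0.641). For lists the counts were 280, 28, 31 and 1, the last being histones between PacBio and Illumina with fry (adjusted p = 0.0269). For platform ratios of named genes 1054 were kept and 3 lost, and for differences between folds 159 and 43. A named gene that was not tested in an alternative was left out of these tallies. Thinning therefore added few: 48 kept, 2 lost and 1 changed sign between the lines, against 260 kept with RLE scaling. For platform ratios it added 50 kept and 1 lost, against 84 kept with RLE scaling, and for differences between folds only 2, which were lost. Thinning to the smallest library total left 291, 291 and 136 genes called between the lines in Illumina, ONT and PacBio. It left 928, 652 and 1320 for ONT over Illumina, PacBio over Illumina and PacBio over ONT. For the interactions it gave 1, 0 (edgeR, with 70 at an unadjusted p below 0.05, and at full depth DESeq2 223 and limma-voom 3890) and 18. Fewer counts are the construction of this alternative, and they also change which genes pass the filter. Called genes of the PacBio and ONT interaction rose from 5 to 18, while those at an unadjusted p below 0.05 (edgeR) fell from 996 to 218. Why the calls rose was not tested. PacBio calls between the lines were 133 with DESeq2, 88 with limma-voom, 971 without a filter (34.0% higher, against 50%), 50 with a replicate block and 63 with close pairs summed, and 24 (without H1975 replicate 2) to 336 (without HCC827 replicate 3) when 1 sample was left out. With the same identifier version only, 13203 genes were called for ONT over Illumina and 901 for its interaction, 5041 for PacBio over Illumina and 2 for its interaction, with fewer genes tested. The ONT and Illumina interaction gave 3126 without a filter, 3109 with the block and 1101 (without H1975 replicate 3) to 2765 (without HCC827 replicate 3) with 1 sample left out. The PacBio and Illumina interaction gave 223 with DESeq2, 3890 with limma-voom, 9 without a filter, 32 with the block and 0 to 3 with 1 sample left out. The PacBio and ONT interaction gave 226, 5721, 20, 99 and 0 to 2, and PacBio over ONT gave 20139 with limma-voom. The cause of these shifts was not tested. The block between platforms changed no other call by over 1.5 times. Lists called with an estimated correlation and with fry were 0 and 23 in Illumina, 3 and 19 in ONT and 0 and 6 in PacBio between the lines, and 2, 2 and 0 with an estimated correlation between platforms. Over genes called in both, PacBio and ONT folds had r = 0.957. The length slope of PacBio over Illumina was -0.0560 at a mean count of 50 or more; with 1 sample left out slopes ranged from -0.573 to -0.568 (ONT over Illumina), -0.291 to -0.242 (PacBio over Illumina) and 0.0652 to 0.0866 (PacBio over ONT), where 5 samples give no exact p below 0.0625. The median shift of genes from the main fit was 0.65 (limma-voom) and 0.25 (DESeq2) for PacBio over Illumina, and 4.91 and 3.76 for PacBio over ONT. Both methods change the whole fit, so these shifts cannot be put down to scaling. RLE, which changes the scaling alone, gave 0.19 for PacBio over Illumina and -0.12 for PacBio over ONT. It gave -0.11 for the ONT and Illumina interaction and 0.30 for the PacBio and Illumina interaction. Thinning moved shared genes by a median of -0.55, -0.64 and 0.01 between the lines in Illumina, ONT and PacBio. For ONT over Illumina, PacBio over Illumina and PacBio over ONT the shifts were -2.52, 1.00 and 2.59. The calls left after thinning therefore carry such shifts as well as the lower depth. PacBio depth limits its test between the lines to 901 genes.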

Other observations

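The test without chromosome 19 and clustered families and the random orders of genes without exon overlap were tests chosen only after the result was seen. Zinc finger genes of chromosome 19, a clustered family of transcriptional repressors, had a log2 fold below 0, called or not, in 222 of 249 by Illumina (median -1.55) and in 215 by ONT (-1.40). On other chromosomes the fold of zinc finger genes was below 0 in 161 of 265 by Illumina (-0.34) and in 150 by ONT (-0.15). In windows of 20 genes, those from ZNF577 to ZNF701 (chromosome 19, 51804816 to 52587174) had a median of -2.46 in Illumina and -2.36 in ONT. The window from HOXB3 to KAT7 (chromosome 17, 48548870 to 49835026) had 2.67 and 2.03, that from RAB4B to CEACAM6 (chromosome 19, 40778216 to 41772211) 2.07 and 2.30, and that from RELCH to RTTN (chromosome 18, 62187255 to 70205726) -1.89 and -1.67. Of 742 windows 6 lay above and 8 below the range of 1000 random gene orders.

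Folds of genes 10 to 20 places apart on a chromosome were correlated (r = 0.0829 in Illumina; highest of 1000 random orders 0.00706), and window medians of ONT and Illumina had r = 0.957. Reads shared between overlapping neighbours are argued against as the whole cause, since r was 0.0425 among 7237 genes without exon overlap (highest of 1000 random orders of these genes 0.0121). Clustered families are argued against as the whole cause, since r was 0.0682 without them and without chromosome 19 (12950 genes, highest random order 0.00801). A difference in gene dosage between the lines may contribute and remains a hypothesis, because no copy numbers were used here.

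Cell line folds of PacBio had a slope of 0.806 on ONT folds, but their SD was 0.927 of that of ONT folds, the slope over genes called in both was 0.946, and ONT folds had a slope of 0.867 on Illumina folds. Whether PacBio folds are compressed is therefore open. Illumina thinned to PacBio totals gave a higher slope on ONT folds, 0.939 ± 0.0150 (mean ± SD over 5 thinning draws). The slope of Illumina at full depth over the same genes was not measured, so whether low depth contributes is open. Counting clustered sequences instead of reads may contribute. Over bins of ONT level the log2 PacBio count rose by 0.0561 ± 0.0907 per log2 unit, against 0.440 ± 0.0654 for thinned Illumina, and by 0.133 ± 0.0688 against 0.583 ± 0.0499 among genes of 3000 to 5000 nt (mean ± SD, n = 6 RNA samples). Over bins of Illumina level the slopes were 0.637 ± 0.0874 for PacBio and 1.06 ± 0.0831 for ONT, so the size depends on which platform sets the bins.

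The platform ratio fell with gene length for both long-read platforms over Illumina, by -0.571 for ONT and -0.258 ± 0.0872 for PacBio per log2 unit, but for PacBio by -0.0560 ± 0.0927 at a mean count of 50 or more (exact sign-flip p = 0.219, above 0 in 1 of 6 RNA samples). Several Illumina fragments per long transcript may contribute for ONT, and for PacBio this is open. A slope of 0.0738 ± 0.0355 for PacBio over ONT cannot tell whether long molecules were lost in ONT relative to size-selected PacBio. Many of the genes in it had 0 PacBio counts. Per library, over its genes with 10 or more counts, the slope of log2 CPM (on library totals) on length was lower in PacBio (0.0349 ± 0.00199) than in ONT (0.307 ± 0.0515), but at equal depth higher (0.0390 ± 0.00567 and -0.0206 ± 0.0143), so that measure depends on depth. Both remain open, and no biological explanation was tested.

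Genes that overlap another on the opposite strand took 44.03% of counts in PacBio, 32.4% in Illumina and 28.3% in ONT. Among overlapping pairs with 60 or more counts in each gene, exactly equal counts in all 6 libraries were found in 23.9% of 452 pairs in PacBio, 0.198% of 8070 in Illumina and 0.378% of 8470 in ONT. Exact equality is easier at low counts, so these shares do not rank the platforms. Across pseudogenes, which are not independent replicates, pseudogene and parent folds had r = 0.719 in ONT (2966 pseudogenes) and 0.677 in Illumina (2129).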
